A study of Arabidopsis thaliana with 6 samples.

How the data were processed

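Messenger RNA abundance was measured in 6 individual Arabidopsis thaliana plants of the Columbia-0 accession. 3 plants were wild type, numbered 22, 23 and 24 in the labels, and 3 were msh1 memory plants, numbered 31, 32 and 33. MSH1 encodes a MutS-type protein targeted to plastids and mitochondria, and msh1 memory plants are, as background, progeny of plants in which MSH1 was suppressed that no longer carry the suppressing transgene but keep an altered phenotype. Per the labels' protocols, seeds were stratified at 4 °C for 2 days, plants were grown at 22 °C under light of 120 to 150 µmol per square metre per second, and whole plants were taken at early bolting. Total RNA was purified with a NucleoSpin kit and libraries were made with the TruSeq RNA v2 kit, which does not mark strand, and read as 150-bp reads. The plant numbers are not shared between the groups, so no pairing was used.

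The deposited files hold whole-number read counts per gene, 1 file per plant, which the authors made before deposit. The submitters' processing notes name TAIR10 and DESeq2. The aligner, the program that counted reads, the treatment of reads that map to several places and the use of strand are not given in the sources used here. Reads of near-identical gene copies, of overlapping genes and of antisense partners therefore cannot be told apart with certainty. Every file lists the same 33602 loci, and the 133 plastid and 146 mitochondrial loci are at 0 in every library, so organelle transcripts were not analysed here.

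Gene symbols, biotypes and positions were taken by locus identifier from the annotation of assembly TAIR10.1, which matched 32835 loci and left 767 unmatched, 279 of them the organelle loci. The files hold no coordinates. All positions given are 1-based positions in TAIR10.1.

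Library totals ranged from 4060216 to 5806617 counts, so 1 CPM stands for 4.06 to 5.81 counts, and a count of 0 in a library allows up to 0.517 to 0.739 CPM (3 counts). These floors cover counting error only. The chi-square per degree of freedom between libraries of 1 group was at least 3.18, above sampling noise in every pair.

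Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 16928 genes, and libraries were scaled with the trimmed mean of M values (TMM). The quasi-likelihood test (robust glmQLFit, glmQLFTest, two-sided) compared the groups, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are msh1 memory minus wild type. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. Values per group are means of TMM-scaled CPM with the SD over 3 plants. The 6 plants are separate individuals.

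22 gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, two-sided and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The lists cover dawn-phased and evening-phased clock genes, flowering time, markers of flower organs, roots and dividing cells, salicylic acid defence, jasmonate and ethylene defence, abscisic acid and drought, cold, heat shock, mitochondrial stress, nuclear photosynthesis genes, DNA methylation and silencing, auxin response, anthocyanin and flavonoid synthesis, aliphatic glucosinolates, senescence, rapid touch and wound response, phosphate starvation, iron deficiency and iron storage. 332 list places were filled by tested genes. Lists of plastid-encoded and mitochondrion-encoded genes had no counts, and a list of transposable element genes was not run because the annotation used does not mark that type. The lists, tests, named-gene rule and most alternatives were fixed before the data were examined.

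Positions of called genes were compared with 10000 random placements of the calls over the tested genes (one-sided permutation tests), for the fullest window of 100 consecutive tested genes and for adjacent genes changed in 1 direction.

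The named genes are MSH1, then, among called genes whose groups do not overlap and whose higher group averages at least 5 CPM, the 10 with the largest positive and the 10 with the largest negative log2 fold change, then up to 4 called members with the smallest p from each list, or the 1 member with the smallest p where no member was called. Genes whose values are given outside this rule are said to be so in the Results, and the further genes under Other observations are outside it.

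The alternatives were size factors of DESeq2 in edgeR, library totals and upper-quartile scaling, 2 other filters, DESeq2 1.42.0, limma voom, a fit without robust estimation, a test against a 1.5-fold change, a threshold of 0.01, removal of GC content and length trends, and leaving out each plant in turn. Removing organelle genes would have changed nothing and was not run. On counts simulated from the libraries' means and dispersions, with 200 of 16928 genes changed, the comparison of msh1 memory with wild type recovered 51% of 100 genes changed 2-fold and 91% of 100 genes changed 4-fold, with 11 false calls. With no gene changed it made 6 calls. Figures were drawn with matplotlib 3.10.9.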

Results

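Transcript levels were compared between 3 wild-type plants and 3 msh1 memory plants of Arabidopsis, each sequenced as 1 library. The comparison asks which transcripts differ in a line with a past loss of MSH1 function relative to its isogenic wild type. The libraries held 5459895, 5634049 and 5806617 counts in wild-type plants 22, 23 and 24, and 4608164, 5053439 and 4060216 counts in memory plants 31, 32 and 33. Between 19614 and 20465 genes had reads in a library, and 16928 genes were tested.

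Wild-type plant 23 stood apart from the other 5 plants, and the 3 memory plants lay together on the first and second principal components but not on the third. Pearson correlations of log2 CPM across genes were 0.975, 0.976 and 0.970 among memory plants, and 0.945, 0.973 and 0.933 among wild-type plants. Wild-type plant 23 lay at 68.38 on the first principal component, which held 41.7% of the variance, while the other 5 plants lay between -25.01 and -4.46. Among the genes with the largest weights on that component were the cutin synthesis gene PEL3 (also DCR; 1.35 CPM in plant 23, 47.7 and 63.9 CPM in plants 22 and 24) and the anthocyanin synthesis gene LDOX (1.16 CPM in plant 23, 22.1 and 26.3 CPM in plants 22 and 24). The second component held 28.2% of the variance and placed wild-type plants 22 and 24 at -25.12 and -44.85 and the memory plants between 15.22 and 22.86, with plant 23 at 9.68. The third held 11.5% and spread the memory plants most, at 1.26, -29.26 and 26.06 for plants 31, 32 and 33, with the wild-type plants between -4.14 and 7.65.

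**Figure D1:**
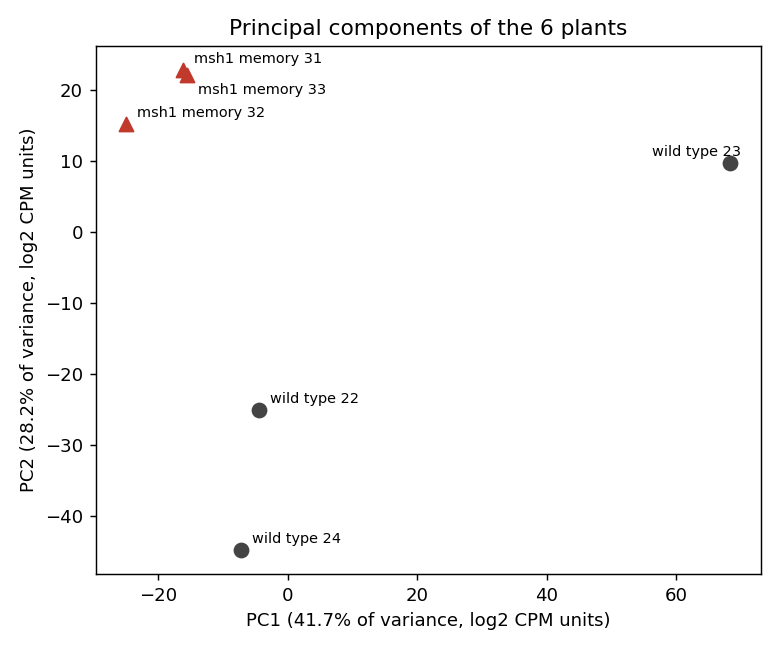
First and second principal components of log2 CPM over the tested genes, with circles for wild-type plants and triangles for memory plants. Plant 23 lies at 68.38 on the first component, and the 3 memory plants lie together between 15.22 and 22.86 on the second.

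MSH1 (AT3G24320, chromosome 3, 8822924 to 8829728) did not differ detectably between the groups. It stood at 14.1 ± 2.94 CPM in wild type and 14.2 ± 2.34 CPM in memory plants (SD, n = 3 each), with 97, 65 and 70 reads in plants 22, 23 and 24 and 59, 65 and 73 reads in plants 31, 32 and 33. The log2 fold change was 0.009 with an SE of 0.221 (edgeR adjusted p = 0.991).

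More genes were lower than higher in the memory plants. Of 16928 genes, 308 passed the threshold of 0.05, 76 of them higher and 232 lower, and 41 of the higher and 148 of the lower genes changed at least 2-fold. All 308 had groups that did not overlap. Among all tested genes 3341 (19.7%) had groups that did not overlap, where chance gives 10% for 3 against 3. Without plant 23 there were 1019 calls, 457 higher and 562 lower. Without plant 31, 32 or 33 there were 34, 65 and 38 calls, and leaving out plant 22 lowered the higher genes to 33.

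Among the genes with the largest decreases was PRPL11 (AT1G32990, chromosome 1, 11955656 to 11957402), the nuclear gene for plastid ribosomal protein L11. It fell from 153.6 ± 8.05 CPM in wild type to 15.01 ± 4.014 CPM in memory plants (SD, n = 3 each), a log2 fold change of -3.35 with an SE of 0.192 (edgeR adjusted p = 1.24e-05). AT1G07050, which encodes a CCT motif protein (chromosome 1, 2163575 to 2165261), fell from 10.02 ± 2.497 to 0.650 ± 0.229 CPM, a log2 fold change of -3.91 with an SE of 0.420 (edgeR adjusted p = 8.95e-04). The other 8 of the 10 largest decreases were FKF1 (log2 fold change -3.71), the ethylene response factor genes ERF105 (-3.36) and ERF5 (-3.11), the defensin genes PDF1.2C (-2.89) and PDF1.2B (-2.77), AT1G70640 with a PB1 domain (-2.69), BT2 with BTB and TAZ domains (-2.65) and the acyltransferase gene AACT1 (-2.53). Their edgeR adjusted p-values lay between 6.04e-05 and 0.0222. FKF1 and ERF105 overlap a neighbouring gene in the annotation, so their reads may in part be shared.

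Of the genes that rose, AT3G24420, an alpha/beta hydrolase gene (chromosome 3, 8862813 to 8865239), had the largest fold change in the named set, from 0.773 ± 0.542 to 7.65 ± 0.405 CPM (SD, n = 3 each; log2 fold change 3.25, SE 0.458, edgeR adjusted p = 0.00455). The oxidoreductase gene AT3G04650 rose from 6.49 ± 1.04 to 30.6 ± 2.28 CPM (log2 fold change 2.23, SE 0.194, edgeR adjusted p = 2.08e-04). The precursor of the microRNA miR163, MIR163 (AT1G66725), rose from 5.16 ± 0.282 to 21.2 ± 2.27 CPM (log2 fold change 2.04, SE 0.210, edgeR adjusted p = 6.24e-04). The other 7 were the cellulose synthase-like gene CSLA01 (log2 fold change 2.58), the snoRNA locus AT3G47348 (2.51), the non-coding RNA locus AT4G02005 (2.28), the cysteine proteinase gene AT2G27420 (2.27), AT5G66740 with a DUF620 domain (2.12), the Serinc-domain gene AT3G24460 (2.08) and the cinnamoyl-CoA reductase gene CCR2 (1.99). Their edgeR adjusted p-values lay between 0.00597 and 0.0308. AT3G24460 and CCR2 overlap another annotated gene.

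Evening-phased clock genes were lower in memory plants, and 3 dawn-phased clock genes were higher. Of 10 tested evening members 7 fell, none rose, and all 10 had negative fold changes, with a median of -1.97. GRP7, an RNA-binding protein gene under clock control, fell from 257.4 ± 10.4 to 52.2 ± 6.52 CPM (SD, n = 3 each; log2 fold change -2.30, SE 0.149, edgeR adjusted p = 2.34e-05). PRR5, a repressor of the morning clock genes, fell from 78.8 ± 14.0 to 14.0 ± 1.79 CPM (log2 fold change -2.48, SE 0.179, edgeR adjusted p = 3.99e-05). FKF1, a blue-light receptor that acts in photoperiodic flowering, fell from 40.5 ± 12.2 to 3.09 ± 0.234 CPM, and PRR3 fell from 14.7 ± 3.47 to 3.38 ± 0.492 CPM. All 10 were lower when adjusted over the list alone. The list passed with camera (adjusted p = 1.06e-48), with an estimated correlation (adjusted p = 0.0269) and with fry (adjusted p = 0.00710). All 7 calls remained without plant 22, 23 or 24, and 5 of the 7 without plant 31, 32 or 33. Without plant 23, 10 of 11 tested members were past the threshold. DESeq2 and edgeR without a low-count filter called 10 of 13 members lower, and the 1.5-fold test 4.

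Of 11 tested dawn members 3 rose and none fell, 10 had positive fold changes, and the median was 0.64. LHY, a core repressor of the evening genes, rose from 22.4 ± 3.24 to 52.2 ± 8.33 CPM (SD, n = 3 each; log2 fold change 1.22, SE 0.171, edgeR adjusted p = 0.0044), RVE1 rose from 10.9 ± 3.00 to 26.2 ± 5.26 CPM and LNK3 from 59.9 ± 8.24 to 105.8 ± 2.65 CPM. CCA1, the partner of LHY, was not called and is named outside the rule, at 122.0 ± 36.7 and 209.3 ± 4.40 CPM (edgeR adjusted p = 0.0640). Over the list alone 6 members were higher. The list passed with camera (adjusted p = 1.38e-09) but not with an estimated correlation (adjusted p = 0.317). Without plant 23, 10 members were past the threshold, without plant 22, 31 or 32 1 was in each case, and without plant 33 none was. DESeq2 and edgeR without a low-count filter called 5 of 12 members higher, and the 1.5-fold test none. LNK3 and RVE1 overlap a neighbouring gene.

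**Figure D2:**
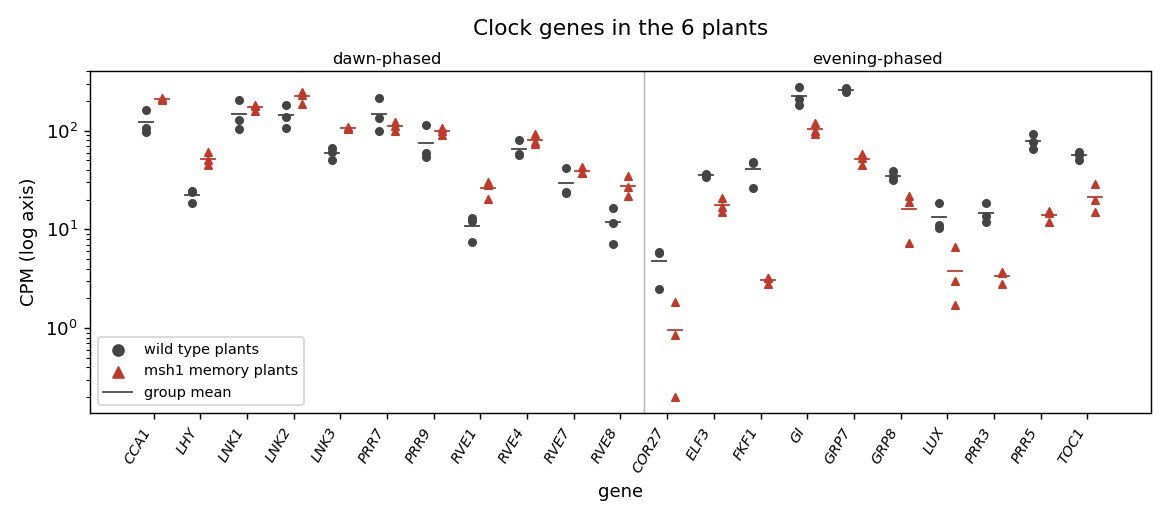
CPM on a log axis for the tested dawn-phased and evening-phased clock genes, with 1 point per plant (circles, wild type; triangles, memory) and lines for the group means. All 10 evening-phased genes have lower means in memory plants, and 10 of the 11 dawn-phased genes have higher means.

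Rapid touch and wound genes and cold-regulated genes had lower values in memory plants, and the number of single members that passed depended on the method. Of 19 tested touch and wound members 3 fell and all 19 had negative fold changes, with a median of -2.26. ERF105 fell from 12.6 ± 7.19 to 1.202 ± 0.586 CPM, ERF5 from 21.7 ± 13.2 to 2.47 ± 0.9575 CPM and the zinc finger gene SZF2 from 73.5 ± 32.0 to 25.3 ± 3.52 CPM (SD, n = 3 each; edgeR adjusted p = 0.0072, 0.0222 and 0.0343). With adjustment over the list alone 14 were lower. The list passed with camera (adjusted p = 3.65e-18) but not with an estimated correlation (adjusted p = 0.317). Its mean log2 CPM was 5.85 in wild-type plant 24, 4.26 and 3.98 in plants 22 and 23, and between 2.72 and 2.92 in memory plants. Without plant 24, 10 of 18 tested members were past the threshold at a median of -1.15, without plant 23 6 were, and without plant 31, 32 or 33 none was, at medians of -2.17, -2.30 and -2.08. DESeq2 called 13 of 22 members lower, edgeR without robust estimation 10, with GC and length trends removed 5, with library totals 2, and voom and the 1.5-fold test 1 each.

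Of 14 tested cold-regulated members 3 fell and all 14 had negative fold changes, with a median of -1.36. COR15B, which encodes a chloroplast stroma protein, fell from 243.2 ± 88.8 to 64.0 ± 7.84 CPM, KIN2 from 231.0 ± 67.4 to 98.2 ± 11.9 CPM and COR413-PM1 from 583.5 ± 89.5 to 314.5 ± 61.4 CPM (SD, n = 3 each; edgeR adjusted p = 0.00985, 0.0135 and 0.0305). With adjustment over these 14 genes alone 13 were lower. COR27 and COR28 of this list are also members of the evening-phased clock list, so the 2 lists are not independent. The list passed with camera (adjusted p = 8.27e-22) but not with an estimated correlation (adjusted p = 0.195). COR15B overlaps another annotated gene, and COR15B and KIN2 have close paralogs, COR15A and KIN1, with which reads may be shared. Without plant 22 there were 11 calls, without plant 23 or 24 2 in each case, and without plant 31, 32 or 33 none, at medians of -1.70, -1.40 and -1.35. DESeq2 called 13 of 15 members lower, edgeR without a low-count filter 8, without robust estimation or with GC and length trends removed 5 each, and the 1.5-fold test none. In the abscisic acid and drought list, RD29A, which cold and drought induce, fell from 701.5 ± 250.6 to 238.3 ± 61.9 CPM (edgeR adjusted p = 0.0384), while the 14 other tested members did not pass and the list did not (camera adjusted p = 0.792, direction down with a median of 0.10; 1 higher and 4 lower when adjusted over the list alone). Of this list 2 members were lower without plant 22, RD29A among them. Without plant 23, 2 were higher and 1 was lower, but the RD29A call ended, and none passed without any other plant. With library totals the RD29A call ended (adjusted p = 0.0539, log2 fold change -1.47 against -1.558) and 1 member was higher, DESeq2 called 3 lower, edgeR without a low-count filter or without robust estimation 2 each, and the 1.5-fold test none.

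Of 26 tested jasmonate and ethylene members 5 fell and none rose, with a median of -0.40. JAZ1, a repressor of jasmonate signalling, fell from 64.6 ± 22.4 to 16.5 ± 2.83 CPM (SD, n = 3 each; log2 fold change -1.96, SE 0.248, edgeR adjusted p = 0.0044). The defensin genes PDF1.2A, PDF1.2B and PDF1.2C fell from 50.25 ± 5.352 to 18.8 ± 7.34, from 10.8 ± 5.31 to 1.58 ± 0.285 and from 11.2 ± 1.41 to 1.45 ± 1.09 CPM (edgeR adjusted p = 0.0115, 0.00681 and 0.00546), and reads may be split among these near-identical copies. The fifth call, outside the naming rule, was ORA59, the ethylene response factor that activates them (edgeR adjusted p = 0.0434). JAZ1 and PDF1.2B were highest in wild-type plant 24 (89.5 and 16.9 CPM), as the touch and wound list was. PDF1.2A and PDF1.2C were highest in plant 22 (55.6 and 12.8 CPM). Whether handling or time of harvest bears on these genes was not tested. When adjusted over the list alone, 9 were lower. The list passed with camera (adjusted p = 1.51e-08) but not with an estimated correlation (adjusted p = 0.401). Without plant 31 no member passed, without plant 32 3 did and without plant 33 1 did. DESeq2 called 8 of 30 members lower, and voom and the 1.5-fold test 3 each.

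Anthocyanin and flavonoid genes had higher values in memory plants. All 16 tested members had positive fold changes, with a median of 0.70, and 1 rose, F3H, which encodes flavanone 3-hydroxylase, from 15.4 ± 4.13 to 35.5 ± 3.03 CPM (SD, n = 3 each; fold change 2.30, SE of its log2 value 0.202, edgeR adjusted p = 0.0108). F3H overlaps another annotated gene. Over the 16 genes alone 7 were higher. The list passed with camera (adjusted p = 4.94e-09) but not with an estimated correlation (adjusted p = 0.353). Its mean log2 CPM was 2.18 in wild-type plant 23, 4.17 and 4.22 in plants 22 and 24, and between 4.42 and 4.80 in memory plants, and without plant 23 the median was 0.45. Without plant 23 there were 3 calls, without plant 24 2, and without plant 31, 32 or 33 none. DESeq2, edgeR without a low-count filter and removal of GC and length trends gave 2 calls each, and the 1.5-fold test none.

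Of 18 tested flowering-time genes 2 rose and 2 fell. The floral repressor genes TEM1 and TEM2 fell from 98.3 ± 37.3 to 31.9 ± 2.58 and from 92.7 ± 41.1 to 28.2 ± 1.27 CPM, and the floral promoter genes SOC1 and SPL4 rose from 51.4 ± 7.85 to 84.2 ± 5.10 and from 2.90 ± 0.510 to 7.75 ± 1.14 CPM (SD, n = 3 each; edgeR adjusted p = 0.00905, 0.0284, 0.0301 and 0.0460). TEM1 and TEM2 were highest in wild-type plant 24 (141.3 and 137.0 CPM), as the touch and wound list was, and at 55.7 to 85.5 CPM in plants 22 and 23. Whole plants were taken at early bolting. Whether exact stage, tissue make-up, handling or time of harvest bears on these 4 calls was not tested apart from genotype. The other 14 tested members did not pass. The list did not pass with camera (adjusted p = 0.205). With fry for change in either direction 7 lists passed: flowering time and phosphate starvation (adjusted p = 4.32e-04 each), salicylic acid defence (5.4e-04), evening clock (7.21e-04), abscisic acid and drought (0.00448), jasmonate and ethylene (0.00589) and dawn clock (0.0222). Adjusted over the list alone, 3 were higher and 2 lower. Without plant 31, 32 or 33 no flowering-time gene passed, without plant 22 1 was lower, and without plant 24 2 were lower, with none higher in either case. With library totals 1 was lower, with voom or removal of GC and length trends 1 was higher, and with the 1.5-fold test none passed. SPL4 overlaps another annotated gene.

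Flower organ markers were mostly too low to test, and their summed reads, which were not tested, were higher in memory plants. Of 21 flower organ markers 2 could be tested (camera adjusted p = 0.792, direction down), with LAP6 at 3.25 ± 0.911 and 2.14 ± 0.375 CPM (SD, n = 3 each). The 19 untested flower markers had at most 20 reads each in a library and summed to 2.01, 1.60 and 4.99 CPM in plants 22, 23 and 24 (11, 9 and 29 reads) and 7.81, 9.50 and 14.3 CPM in plants 31, 32 and 33 (36, 48 and 58 reads). Among these, chosen after their values were seen, AP3 had 0 reads in each wild-type plant and 4, 7 and 4 in plants 31, 32 and 33, and SEP3 had 0, 0 and 10 reads against 10, 8 and 20, while PI had 8, 3 and 9 against 2, 8 and 7 and SHP1 had 1, 5 and 1 against 0, 0 and 1. Without a low-count filter edgeR tested 16 flower markers and called none, with 5 at an unadjusted p under 0.05, and DESeq2 called none, with 4. Without plant 24, 1 of 3 tested flower markers was higher.

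The other 3 lists that passed with camera, senescence, phosphate starvation and iron deficiency, did not pass with an estimated correlation. Senescence genes had a median of -0.52, with SAG21 falling from 37.3 ± 14.1 to 16.4 ± 1.91 CPM (SD, n = 3 each; edgeR adjusted p = 0.0434) as the 1 call among 16 (2 over the list alone; camera adjusted p = 0.00162; adjusted p = 0.195 with an estimated correlation). Phosphate starvation genes had a median of 0.27, with the glycerol-3-phosphate transporter gene G3PP1 rising from 44.7 ± 5.47 to 99.1 ± 3.98 CPM (edgeR adjusted p = 0.00238) as the 1 call among 10 (2 over the list alone; camera adjusted p = 0.00221; adjusted p = 0.195 with an estimated correlation). Iron deficiency genes had a median of -0.47 with no call among 7 over all genes and 3 over the list alone (camera adjusted p = 0.00664; adjusted p = 0.439 with an estimated correlation). Without plant 22, 24, 31, 32 or 33 no senescence gene passed, and without plant 23 3 did. The SAG21 call also ended with library totals (adjusted p = 0.0779), voom (0.0957), upper-quartile scaling and the 1.5-fold test, while DESeq2, edgeR without a low-count filter and removal of GC and length trends gave 2 calls each. The number of phosphate starvation calls was 2 without plant 23, 1 without any other plant and 0 with the 1.5-fold test. SAG21 overlaps another annotated gene. Without plant 23 the iron deficiency list did not pass with camera (adjusted p = 0.126). OPT3, the iron deficiency member with the smallest p, stood at 210.6 ± 34.4 and 145.2 ± 20.5 CPM (edgeR adjusted p = 0.155).

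**Figure D3:**
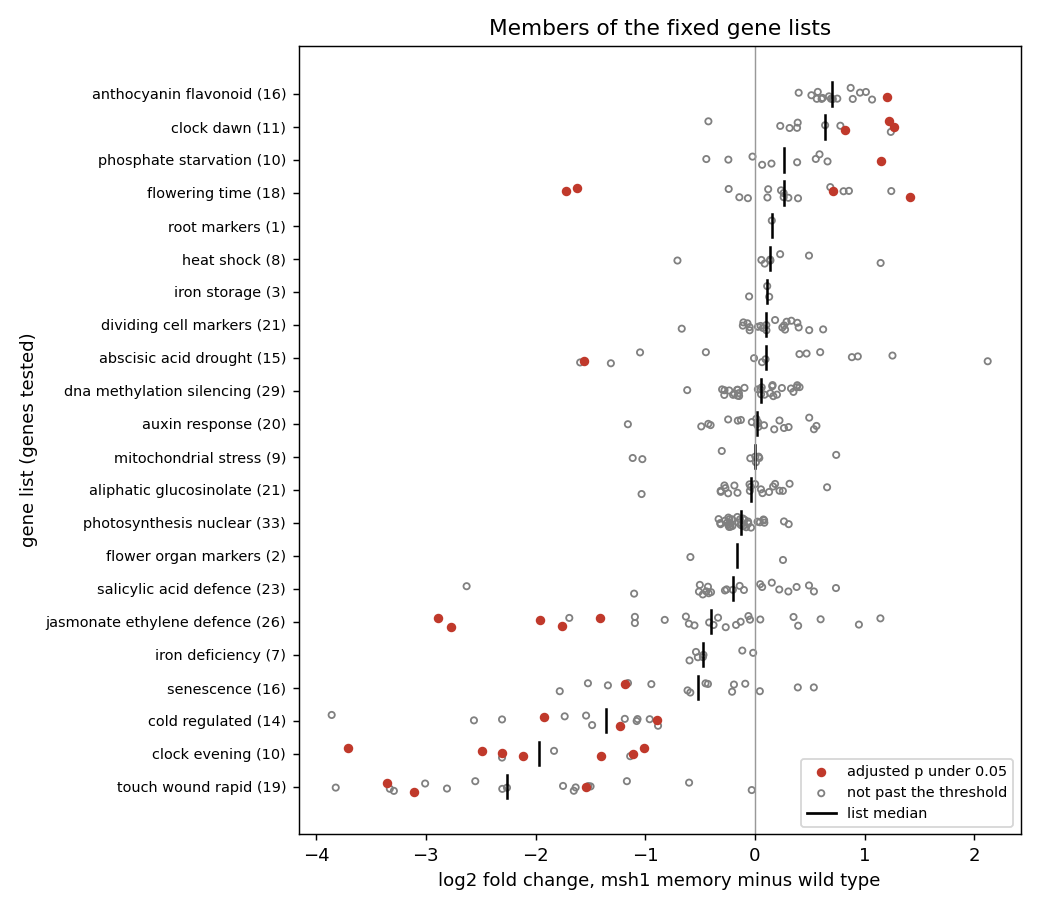
Log2 fold change of each tested member of the 22 gene lists, with filled points for genes past the threshold, open points for the others and a bar at the list median. The evening-phased clock list has 7 filled points and a median of -1.97.

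In the main fit the remaining 11 lists had no called member and did not pass with camera. Adjusted over the list alone, 2 salicylic acid members and 2 mitochondrial stress members were lower and no member of the other 9 lists passed. Leaving out 1 plant changed the camera result of 3 of these lists: salicylic acid defence passed without plant 24 (adjusted p = 0.0189) or 33 (0.00265), nuclear photosynthesis without plant 22 (0.00206), 24 (0.0152), 31 (0.035) or 32 (0.00205), with the opposite direction and no pass without plant 23 (0.676), and dividing-cell markers without plant 22 (0.0118) or 24 (0.00366), again with the opposite direction and no pass without plant 23 (0.0868, at a median of -0.18). Single members passed without plant 23 (1 higher and 3 lower for salicylic acid defence, 2 higher for nuclear photosynthesis, 1 lower for dividing-cell markers) and without plant 22 (1 lower for mitochondrial stress). DESeq2 with all plants called 2 salicylic acid members and 1 mitochondrial stress member lower. edgeR without a low-count filter called 1 salicylic acid member lower. Salicylic acid defence had a median of -0.20 over 23 genes (camera adjusted p = 0.0607), and AZI1 stood at 3.64 ± 0.610 and 0.556 ± 0.609 CPM (SD, n = 3 each; edgeR adjusted p = 0.0774). Nuclear photosynthesis genes had a median of -0.13 over 33 genes (camera adjusted p = 0.0607), with LHCB4.1 at 4721 ± 689.7 and 3800 ± 317.6 CPM. DNA methylation and silencing genes had a median of 0.05 over 29 genes (camera adjusted p = 0.955), with NRPD1 at 13.7 ± 3.95 and 8.96 ± 2.03 CPM. Dividing-cell markers had a median of 0.10 over 21 genes (camera adjusted p = 0.182), with MCM7 at 23.4 ± 8.21 and 29.6 ± 3.12 CPM. Mitochondrial stress genes had a median of 0.004 over 9 genes and a camera direction of down (adjusted p = 0.341), with OM66 at 39.1 ± 16.8 and 18.1 ± 2.66 CPM. Heat shock genes had a median of 0.14 over 8 genes (camera adjusted p = 0.440; fry adjusted p = 0.0273), with BAG6 at 25.04 ± 9.57 and 15.3 ± 3.16 CPM. Auxin response genes had a median of 0.02 over 20 genes and a mean of -0.015 (camera adjusted p = 0.611), with IAA17 at 29.4 ± 6.13 and 41.4 ± 1.46 CPM. Aliphatic glucosinolate genes had a median of -0.04 over 21 genes (camera adjusted p = 0.773), with MAM3 at 7.36 ± 2.14 and 3.57 ± 1.17 CPM. Iron storage genes had a median of 0.11 over 3 genes (camera adjusted p = 0.792), with FER1 at 137.2 ± 9.60 and 150.1 ± 36.3 CPM.

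Most root markers had few reads. Of 22 root markers 1 could be tested (camera adjusted p = 0.773), PYK10, at 12.9 ± 11.1 and 14.4 ± 6.24 CPM (SD, n = 3 each), with 0.19 CPM in plant 23. PYK10 overlaps another annotated gene, as do MCM7 and FER1. Dividing-cell markers had a mean log2 CPM of 1.80 in plant 23, 3.68 and 3.77 in plants 22 and 24, and at least 3.43 in each memory plant.

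**Figure D4:**
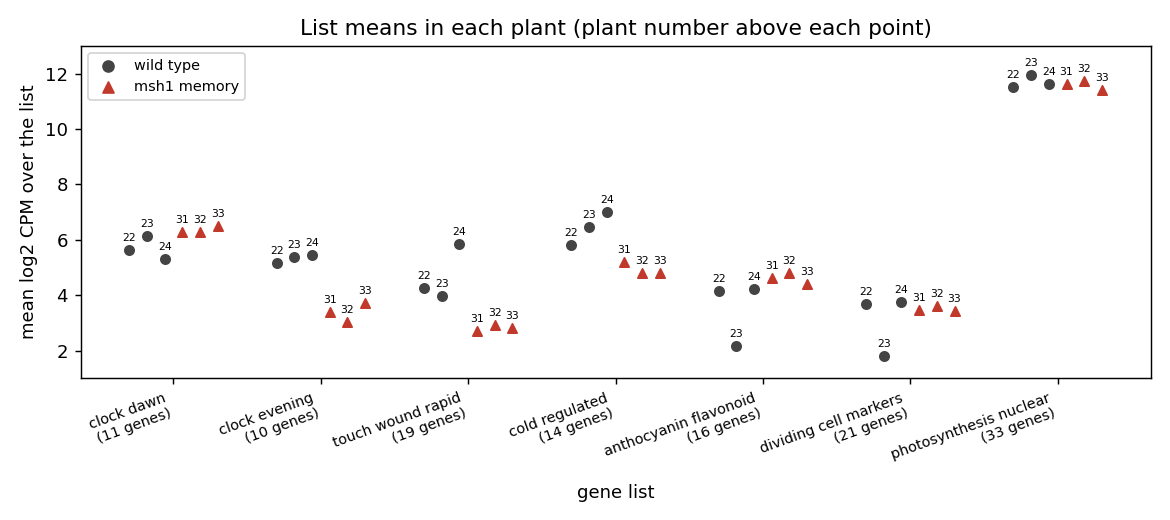
Mean log2 CPM over the tested members of 7 gene lists in each plant, with circles for wild-type plants, triangles for memory plants and the plant number above each point. Plant 23 lies lowest for anthocyanin genes (2.18) and dividing-cell markers (1.80), and plant 24 highest for touch and wound genes (5.85).

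Changed genes lay beside each other more often than random placement gives, while the fullest window of 100 tested genes did not stand out from random placements. The fullest window of 100 consecutive tested genes, on chromosome 1 from 27225665 to 27690307, held 8 calls, where random placements gave a median of 7 (one-sided permutation p = 0.339). 13 adjacent pairs changed in 1 direction, where random placements gave a median of 3 (one-sided permutation p = 1e-04, the smallest that 10000 placements can give). 12 of the 13 pairs were lower in memory plants. In 8 of the 13, the annotated products share their first word, such as the neighbouring receptor genes AT5G41740 and AT5G41750 or the defensin genes PDF1.2A and PDF1.2C, and reads may be shared between such copies. These pairs were named after their values were seen.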

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

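The fit without plants 23 and 24 was chosen after the result was seen. The 308 calls (76 higher, 232 lower) were within 1.5 times under the 3 other scalings, the filter of 1 CPM in 3 libraries, voom, the fit without robust estimation and removal of GC and length trends. The higher share was 24.7% with TMM and 36.2% with library totals (98 of 271), which moved the median of all genes to 0.0742. DESeq2 gave 523 calls (118 higher, 405 lower), no low-count filter 120 higher, the 1.5-fold test 44 (9 and 35), the 0.01 threshold 98 (17 and 81), and the fit without plants 23 and 24, which takes the lone wild-type plant to vary like the memory plants, 128 higher. The cause was not tested, except that the stricter tests ask more of each gene. Leaving out 1 plant gave 34 to 1019 calls, 6 to 457 higher and 24 to 562 lower. Without plant 31 all 34 calls were among the 308. At the depth and number of these plants, 51% of simulated 2-fold changes were recovered. The simulation held no shift shared by many genes of a plant, so this share may not carry over to the real libraries.

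MSH1 stayed past no threshold and its fold change turned sign when single plants were left out (-0.131 to 0.194). FER1 (-0.017 to 0.312) and PYK10 (-0.405 to 0.660), neither called, did so as well. Of the called named genes, 104 of 240 tests that left out 1 plant and 13 of 200 under other settings lost the call, with no change of sign.

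Of the 9 lists past the threshold, only the evening clock held with an estimated correlation and with fry. Heat shock, outside the 9, passed with fry as well. With an estimated correlation the adjusted p was 0.353 for anthocyanin, 0.317 for dawn clock and touch, 0.195 for cold, phosphate and senescence, 0.439 for iron deficiency and 0.401 for jasmonate. With fry it was 0.176 for anthocyanin and touch, 0.157 for dawn clock, 0.122 for cold and senescence, 0.240 for iron deficiency, 0.217 for jasmonate and 0.0527 for phosphate. The estimated correlation was 0.87 for touch, 0.762 for dawn clock, 0.646 for cold, 0.626 for anthocyanin, 0.493 for jasmonate and 0.436 for iron deficiency. For these lists the preset of 0.01 understates how far members vary together, so the preset p-values are too small. It was 0.293 for the evening clock. For senescence and phosphate it was 0.019 and 0.028, near the preset, and why they lost the threshold was not tested. Leaving out 1 plant gave 1.44e-05 to 0.126 for iron deficiency, the highest without plant 23, and the other 8 lists stayed past the threshold. Windows of 50 genes gave a permutation p of 0.937 against 0.339. Removing organelle genes was not run, since they have no counts.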

Other observations

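The tests on single plants and without plants 23 and 24, on scalings, depth, time of harvest and handling, the product-name and biotype tests, and the genes near MSH1 and PRPL11 were chosen after the results they bear on were seen.

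Non-coding RNA loci were over-represented among the genes that rose, relative to all other genes. Of 221 tested, 12 rose and 2 fell, against 64 that rose among 16707 other genes (Fisher's exact test, two-sided p = 2.7e-10). Against protein-coding genes under 600 bases, of which 3 of 145 rose and 5 fell, Fisher's exact test gave a two-sided p of 0.176 for all 221 and 0.0208 for the 46 non-coding loci under 600 bases, of which 5 rose. The 221 loci had a median length of 1246 bases and these coding genes 530, so the comparison of all 221 is not matched for length. Besides MIR163, MIR167d rose from 9.08 to 31.3 CPM (edgeR adjusted p = 0.00432) and MIR414 from 11.0 to 21.4 CPM (edgeR adjusted p = 0.0382). Median log2 fold changes were 0.77 for 13 microRNA loci, 0.80 for 15 snoRNA loci, 0.36 for 74 ncRNA loci, 0.09 for 114 lncRNA loci and 0.19 over all 221, against 0.17 for 145 protein-coding genes under 600 bases and 0.01 for all protein-coding genes. 4 of the 12 overlap another gene. With GC and length trends removed, 57 genes of all types were higher, against 76 in the main fit. How many of the 12 loci were among the 57 is not given here, so an effect of length is not separated from one of gene type. No product name with at least 10 tested genes passed in 360 tests over both directions. The smallest adjusted p by Fisher's exact test was 0.187, for the product names snoRNA and major facilitator transporter. Of 10 loci with the product name snoRNA, 2 rose where 0.0449 were expected. Of 84 major facilitator transporter genes, 6 fell where 1.15 were expected.

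2 of the 20 tested genes nearest to MSH1 on chromosome 3, AT3G24420 and AT3G24460, rose, starting 39.9 and 62.9 kb from the start of MSH1 (one-sided permutation p = 0.0522). Both are among the 10 largest increases named above, and this test counts calls without regard to their size. On the same side, AT3G24490 at 87.5 kb was not called (log2 fold change 0.97, edgeR adjusted p = 0.064), nor was any other of the 20. Of the 10 tested genes nearest in order to PRPL11, GBSS1, the granule-bound starch synthase gene, was the only call (log2 fold change 1.01, edgeR adjusted p = 0.00702).

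The real grouping of the 6 plants gave 308 genes and the highest of the other 9 splits gave 1, and 1 of the 10 splits gave as many. For lists past the camera threshold, the real grouping gave 9 and the highest other split 10, and 5 of the 10 splits gave at least 9. With 10 splits no share can fall under 0.05, so these counts do not exclude chance. In the other 9 splits camera with a preset correlation passed 5 to 10 lists. Those splits put plants of both genotypes in each group, so part of the genotype difference and the shift of plant 23 remain in them. Their list counts therefore do not measure how often camera passes lists where no difference exists. Mixing genotypes also widens the spread within each group, which by itself lowers the number of genes called.

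Of 10 evening-phased clock genes 7 were lower and of 11 dawn-phased genes 3 were higher in memory plants, and the dawn list did not pass with an estimated correlation (adjusted p = 0.317, with 1.11e-18 to 0.317 over the alternatives). For the evening genes a single aberrant plant as the whole cause is argued against. At least 5 of their 7 calls remained whichever plant was left out. The dawn genes are less clear. Their median was at least 0.47 whichever plant was left out, but their calls fell to 1 without plant 22, 31 or 32. Dawn calls fell to 0 without plant 33 and were 10 without plant 23. Which measure decides was not fixed beforehand, so no verdict is drawn for the dawn genes. The choice of scaling is argued against as well, for the scalings run. The 3 others gave median log2 fold changes of all genes between 0.0057 and 0.0742, against 0.0079 with TMM. Such shifts are small beside the evening median of -1.97 and the dawn median of 0.64. All 7 evening and all 3 dawn calls remained under each, but shifts of this size could hardly have ended them, so this adds little. Harvest of the groups at different times of day stays open: 10 of 11 dawn members were positive and all evening members negative, which is what an earlier harvest of memory plants could give, and a genotype effect on the clock could give the same. The sources used here give no harvest times, so the 2 cannot be told apart.

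Of 19 touch and wound genes 3 and of 14 cold-induced genes 3 were lower in memory plants, none passed without plant 31, 32 or 33 although the medians there were -2.30 to -2.08 and -1.70 to -1.35 against -2.26 and -1.36 with all plants, and neither list passed with an estimated correlation (adjusted p = 0.317, with 1.94e-27 to 0.317 over the alternatives, and 0.195, with 3.47e-52 to 0.195). Plant 24, which had the highest touch values, is argued against as the whole cause, since without it the median was -1.15 for touch genes and -1.11 for cold genes, and without plants 23 and 24 it was -1.30 and -0.61 (quartiles -0.91 and -0.41 for cold genes). Handling or harvest that differed between the groups stays open: the touch mean ranged by 1.87 among wild-type plants, as much as the group difference of -1.87 in size, and by 0.20 among memory plants. Time of day stays open too: the order of the wild-type plants in touch mean differs from that in evening clock mean (plants 22 and 23 differ by a median of 0.26 over the touch list, the other way round) and their order in cold mean is the evening one, but their evening clock means lie within 0.27 of each other against a group difference of -1.94, so these orders decide little. COR27 and COR28 are members of both the cold and the evening list, so the means of those lists are not independent. A genotype effect could give the same group difference and was not tested apart from handling, harvest and time of day.

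Wild-type plant 23 had 53 genes, of those averaging at least 5 CPM on the log scale, that lay over 8-fold below the mean of plants 22 and 24, and no other plant had any below the mean of its own group's other plants. Its depth of 5634049 counts was not the lowest, and an epidermis missing as a whole is argued against, since 14 epidermis and cuticle markers had a median log2 difference of -0.30 (quartiles -1.02 and -0.03), from ATML1 at 85.8 CPM against 101.7 and 92.9 CPM to PDF1 at 3.09 CPM against 58.7 and 84.2 CPM. A candidate explanation is that young growing tissue was under-represented. 16 markers of young leaves and the shoot apex had a median difference of -1.78 (quartiles -2.65 and -0.48). They ran from GRF5 at 0 CPM against 3.06 and 5.74 CPM to KAN1 at 19.72 CPM against 14.58 and 16.71 CPM. ANT lay at 5.03 CPM against 17.81 and 18.27 CPM, while GRF1 hardly differed, at 18.95 CPM against 18.53 and 20.36 CPM. Dividing-cell markers, a list fixed earlier and so no part of that test, had -2.29. Less stem stays open, with a median of -0.77 over 8 stem and secondary wall markers. Apart from the make-up of the sample no biological explanation was tested, since the plant shares its genotype with plants 22 and 24.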
